A study of Homo sapiens with 20 samples.

How the data were processed

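The study measured messenger RNA in 2 human lines of MYC-driven medulloblastoma, D458 and D425, after the Mediator kinase CDK8 was lowered, knocked out or inhibited. Per the labels, 20 RNA-seq libraries fell into 8 groups: D458 with a control hairpin (shNull, 3 libraries) or a CDK8 hairpin (shCDK8, 3), D458 with a Cas9 negative control (3) or CDK8 knockout (3), and D425 and D458 with DMSO (2 each) or RVU120, a CDK8/CDK19 inhibitor, for 48 hours (2 each). The dose of RVU120 is not given in the sources used here. Per the labels' protocols, RNA was extracted with RNeasy Mini Plus columns and libraries were made with a SMARTER mRNA-seq kit. Chromatin profiling of the same study was not analysed here.

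Per the submitters' processing notes, GRCh38, STAR 2.4.0.1 and DESeq2 1.22.2 were used. How reads were counted over genes, whether strand was used, and how reads matching several places were handled is not given in the sources used here. The values analysed are 4 tables of the authors' own comparisons, 1 per perturbation, and hold no values per library. Per the file headers, each table gives for every gene the authors' mean normalized count over the libraries of the comparison, a signal after scaling by the authors' size factors. The authors' log2 fold change and its standard error are on the log2 scale, per the file headers. The deposited statistic is a score, and in all 4 tables it equals the log2 fold change divided by its standard error, so the fold changes had not been shrunk. The p-value and the adjusted p-value of each gene are the authors', from the Wald test of DESeq2 with Benjamini-Hochberg adjustment, per the file headers and the submitters' processing notes. Genes for which the authors' table gives no adjusted p were treated as not tested: 4170 in the knockdown, 1792 in the knockout, 3857 with RVU120 in D425 and 3939 with RVU120 in D458. The direction of the RVU120 tables was taken as RVU120 over DMSO from their names; the knockdown and knockout directions were checked on CDK8 itself, and no gene gives such a check for the inhibitor. Columns of per-sample values left unmatched numbered 0.

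The depth of single libraries is not given in the sources used here. The deposited mean normalized counts summed, in units of 1000000, to 47.8 in the knockdown table, 22.4 in the knockout table, 26.2 for RVU120 in D425 and 26.9 for RVU120 in D458. The median standard error of the log2 fold change among genes with a mean normalized count of at least 100 was 0.06, 0.07, 0.15 and 0.11 in the same order. The tables were normalized separately, so tests were made within a table, and levels set across tables are descriptive.

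A gene was called higher or lower when the authors' adjusted p was under 0.05. Gene positions came from GENCODE v29 on GRCh38, matched by symbol. Symbols that a spreadsheet had turned into dates (26 in the knockdown table, 0 in the knockout table, 21 and 23 in the RVU120 tables for D425 and D458) were left out. The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The 33 gene lists cover Mediator, MYC targets, ribosome and translation, cell cycle, stress responses, metabolism, signalling targets, the photoreceptor program of Group 3 medulloblastoma, neuronal and progenitor genes, histones, and markers of astrocytes and oligodendrocytes, fibroblasts, immune cells, and epithelial and endothelial cells. For each list the called members were counted, once over all genes tested and once adjusted over the list alone. The list's deposited statistics were compared with those of the other genes by cameraPR (limma 3.58.1, preset correlation between genes of 0.01, two-sided) for lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the lists of a comparison. No correlation could be estimated without values per library, so each test of a list's statistics, the list added later included, was repeated with a preset correlation of 0.05. Each list's median was also set against 10000 random lists of the same size, each member drawn from the 50 genes nearest in mean normalized count. No limit was set on their distance, and members were drawn independently, so correlation within a list was not allowed for. Replication-dependent histone genes, multi-copy genes such as the GAGE family, and ribosomal protein genes with many processed pseudogenes share sequence with other loci, and their values are uncertain where counting could split reads.

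Pairs of comparisons were set side by side over the genes tested in both. Calls in the same direction were compared with the number expected for independent lists (one-sided Fisher's exact test). That number ignores abundance, so it was also summed over 20 bins of the mean normalized count of both tables. The difference of 2 log2 fold changes was tested by its ratio to the combined standard error, with a normal p-value and Benjamini-Hochberg adjustment; no libraries are shared between comparisons. For genes called the same way in all 4 comparisons, the calls were reassigned among the genes 1000 times within each comparison, and again within 20 such bins. The members of each list among these genes were tested by an exact test within the same bins, with Benjamini-Hochberg adjustment over the lists of a direction.

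Named genes were taken by a rule: the Mediator kinase module genes and MYC; in each comparison the 8 largest increases and 8 largest decreases with an adjusted p under 0.05 and a mean normalized count of at least 100, leaving out clone names and pseudogenes; for each list and direction the 3 called members with the largest statistic; the 10 genes called the same way in all 4 comparisons with the largest smallest change, and 5 per pair; and the 5 genes per pair with the largest statistic of the difference. The values of 1 gene that the rule names are not reported here, and its place was not filled.

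The alternatives tried were an adjusted p under 0.01, an absolute log2 fold change of at least 1, a mean normalized count of at least 100, adjustment over all genes with a p-value, log2 fold changes centred on their median, and p-values from a t distribution with 4 (knockdown and knockout) or 2 (RVU120) residual degrees of freedom. For lists they were ranks or log2 fold changes in place of the statistic, the preset correlation of 0.05 and matched random lists. Random lists matched also on transcript length and GC content, medians by chromosome, counts without chromosome 13 genes, a list of 27 skeletal muscle genes, and the bins of mean normalized count with their tests were added after the data were seen. A t distribution with 2 degrees of freedom lets almost no statistic pass adjustment over so many genes. So 0 calls for RVU120 under it, and 0 calls shared with RVU120, were nearly fixed in advance.

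The steps were tested on simulated data built on the deposited means and standard errors. In the knockdown, 82.5% of simulated changes of 0.5 (log2) and 76.7% of changes of 1 were called among 15380 genes, with 7 of 15101 unchanged genes called. The shares were 57.1% and 68.6% in the knockout (16694 genes; 6 of 16415 unchanged genes called), 40.8% and 65.7% with RVU120 in D425 (14212 genes; 4 of 13933), and 52.8% and 72.8% with RVU120 in D458 (14515 genes; 10 of 14236). The simulated list lowered by 0.15 was called by cameraPR in each comparison, and 0 unchanged lists were called. Simulated genes were drawn independently with normal errors of the deposited size. Correlation between genes and standard errors estimated from few libraries were therefore not tested. Of simulated differences of 1 between comparisons, 64.8% were called for the knockdown and knockout, 66.3% for RVU120 in both lines, 68.3% for the knockdown and RVU120, and 65.7% for the knockout and RVU120. Computing used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3.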

Results

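The data are 20 messenger RNA libraries of D458 and D425, human cell lines of medulloblastoma, a childhood tumour of the cerebellum, driven by the transcription factor MYC. CDK8 and its paralog CDK19 are the kinases of the Mediator kinase module, which binds the Mediator complex and regulates transcription by RNA polymerase II. The study asked what losing or inhibiting CDK8 does to the transcriptome of MYC-driven medulloblastoma cells. It compared shCDK8 with shNull in D458 (3 libraries each), CDK8 knockout with Cas9 control in D458 (3 each), and the CDK8/CDK19 inhibitor RVU120 for 48 hours with DMSO in D425 and in D458 (2 each). Values for genes are log2 fold changes ± standard error with DESeq2 adjusted p, perturbed over control, with the direction of the RVU120 values taken from the names of the tables. The largest increases and decreases named are those among called genes with a mean normalized count of at least 100, leaving out clone names and pseudogenes. Calls of gene lists by cameraPR given with a single adjusted p held at a preset correlation of 0.05 between genes. The depth of single libraries is unknown, and the summed mean normalized counts, in units of 1000000, were 47.8 in the knockdown, 22.4 in the knockout, 26.2 with RVU120 in D425 and 26.9 with RVU120 in D458. The labels do not say that replicates were separate cultures, so the p-values may measure technical spread only.

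CDK8 (chromosome 13, 26254104 to 26405238, GRCh38) fell in both genetic perturbations. In the authors' deposited table it changed by -1.42 ± 0.05 in the knockdown (adjusted p = 6.24e-177) and by -1.60 ± 0.07 in the knockout (adjusted p = 5.36e-108). Its transcript was not called with RVU120, at -0.04 ± 0.15 in D425 (adjusted p = 0.937) and -0.15 ± 0.08 in D458 (adjusted p = 0.135), both from the authors' deposited table. CDK19 (chromosome 6, 110609978 to 110815958) rose by 0.86 ± 0.10 in the knockdown (adjusted p = 4.4e-16) and 0.80 ± 0.14 in the knockout (adjusted p = 1.42e-07) in the authors' deposited table. With RVU120 the authors' deposited table gives CDK19 at 0.08 ± 0.32 in D425 and -0.64 ± 0.27 in D458 (adjusted p = 0.938 and 0.053). Cyclin C, the partner of both kinases, is encoded by CCNC, which fell in the 3 D458 comparisons of the authors' deposited table, by -0.16 ± 0.04, -0.29 ± 0.05 and -0.22 ± 0.08. MYC (chromosome 8, 127735434 to 127741434) went different ways. In the authors' deposited table it fell in the knockdown (-0.24 ± 0.02, adjusted p = 7.26e-21) and stood at 0.02 ± 0.02 in the knockout (adjusted p = 0.577). MYC was at 0.18 ± 0.09 with RVU120 in D425 (adjusted p = 0.247) and rose by 0.55 ± 0.03 with RVU120 in D458 (adjusted p = 1.79e-54), both from the authors' deposited table. The kinase module list had 1 member higher, 2 lower and 3 not called in the knockdown. Its cameraPR call (adjusted p = 0.00352) restates the knockdown, since CDK8, the hairpin's own target, is 1 of its 6 members and has a statistic of -28.64 in the authors' deposited table. With ranks in place of the statistic it was not called (adjusted p = 0.636), and against random lists of like mean count its median lay slightly above theirs (adjusted p = 0.842). In the other comparisons the list was not called, with adjusted p = 0.436 in the knockout, 0.614 with RVU120 in D425 and 0.837 with RVU120 in D458.

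**Figure D1:**
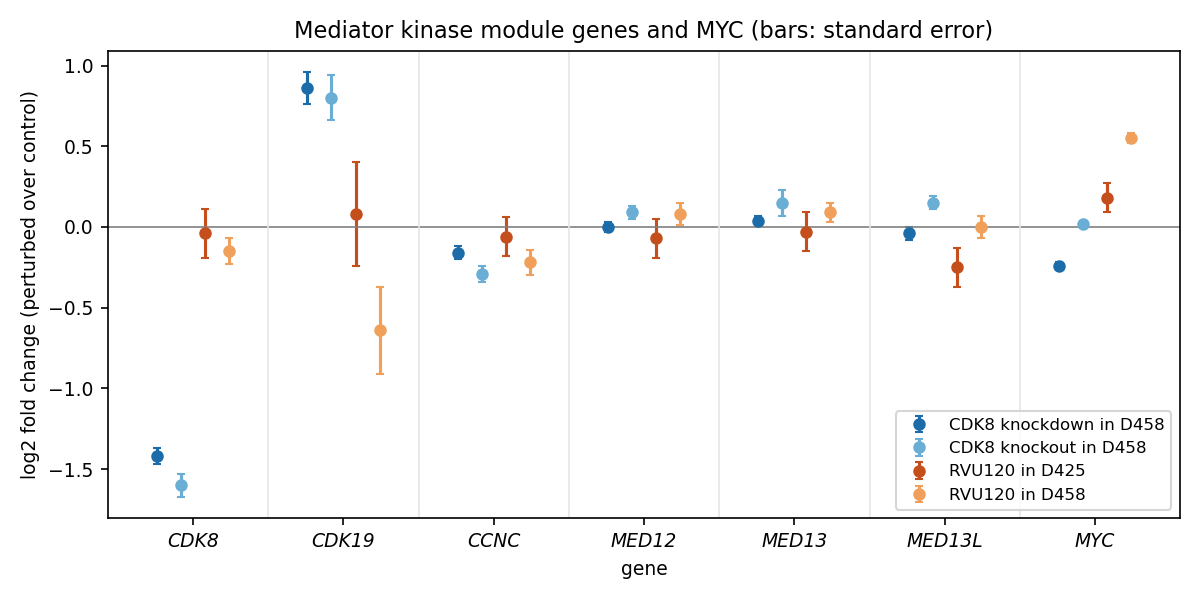
Log2 fold change (y axis, perturbed over control, from the authors' deposited tables) of the Mediator kinase module genes and MYC (x axis) in the 4 comparisons; points are the fitted values and bars the standard errors. CDK8 lies at -1.42 in the knockdown and -1.60 in the knockout, and MYC ranges from -0.24 in the knockdown to 0.55 with RVU120 in D458.

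With CDK8 knockdown in D458, transcripts of the translation machinery were lower by small amounts and some other transcripts higher by much more. Effects of the hairpin beyond CDK8 were not tested. Of 79 tested cytosolic ribosomal protein genes, 57 fell, 0 rose and 22 were not called by DESeq2 (60 fell when adjusted over the list alone). Their median was -0.14 (cameraPR adjusted p = 4.48e-19). RPL4 fell by -0.21 ± 0.02 and RPS2 by -0.24 ± 0.03 in the authors' deposited table. Among translation initiation and elongation factors 28 of 47 fell, 0 rose and 19 were not called (31 lower adjusted over the list alone, median -0.10, adjusted p = 7.73e-15). PABPC4, which encodes a poly(A)-binding protein, fell by -0.88 ± 0.03 in the authors' deposited table (adjusted p = 2.52e-248). Ribosome biogenesis and RNA polymerase I and III genes fell in 55 of 83 members, with 0 higher and 28 not called (63 lower adjusted over the list alone, median -0.12, adjusted p = 5.3e-12).

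MYC target genes also fell in the knockdown, with 41 of 58 lower, 2 higher and 15 not called (43 lower and 3 higher adjusted over the list alone, median -0.14, adjusted p = 8.56e-11). That list shares 21 genes with the ribosome biogenesis list. NPM1, a nucleolar chaperone, changed by -0.16 ± 0.03 and NOLC1 by -0.17 ± 0.02 in the authors' deposited table. Aminoacyl-tRNA synthetases fell in 14 of 22 members, with 0 higher and 8 not called (16 lower adjusted over the list alone, adjusted p = 1.37e-07). Mitochondrial ribosomal protein genes fell in 29 of 75 members, with 0 higher and 46 not called (31 lower adjusted over the list alone, median -0.10, adjusted p = 1.61e-06). Nuclear oxidative phosphorylation genes fell in 32 of 75, with 1 higher and 42 not called (35 and 1 adjusted over the list alone, median -0.09, adjusted p = 2.03e-06). Amino acid and nucleotide synthesis genes also fell (21 of 34 lower, 2 higher, 11 not called, 27 and 2 adjusted over the list alone, adjusted p = 7.49e-08). Of 32 proteasome genes 20 were lower, 0 higher and 12 not called (21 lower adjusted over the list alone, adjusted p = 9.35e-06). Endoplasmic reticulum chaperones were lower in 11 of 23, higher in 1 and not called in 11 (13 and 1 adjusted over the list alone, adjusted p = 1.19e-06).

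Glycolysis and hypoxia genes fell as a list in the knockdown (17 of 33 lower, 4 higher, 12 not called, the same counts adjusted over the list alone, median -0.07, adjusted p = 0.000197). ENO1, an enolase gene, changed by -0.35 ± 0.02 in the authors' deposited table. ATF4 and integrated stress response genes did too (15 of 30 lower, 3 higher, 12 not called, the same counts adjusted over the list alone, median -0.07, adjusted p = 0.0025). TRIB3, a pseudokinase gene of that response, stood at -0.43 ± 0.06 in the authors' deposited table. Mitotic and G2/M genes were slightly higher (16 of 53 higher, 4 lower, 33 not called, 19 and 5 adjusted over the list alone, median 0.05, adjusted p = 0.00927). DNA replication and G1/S genes were slightly lower (19 of 57 lower, 7 higher, 31 not called, 21 and 7 adjusted over the list alone, median -0.05, adjusted p = 0.00927). At a preset correlation of 0.05 neither kept its call (adjusted p = 0.127 each), and with log2 fold changes in place of the statistic the mitotic genes turned downward without a call (adjusted p = 0.632). TGF-beta and SMAD target genes were higher (7 of 20 higher, 2 lower, 11 not called, the same adjusted over the list alone, adjusted p = 0.0371, and 0.127 at 0.05). Against random lists of like mean count the calls of glycolysis (adjusted p = 0.633), ATF4 (0.253), DNA replication (0.53), TGF-beta (0.544) and fibroblast genes (0.253) were lost. With log2 fold changes in place of the statistic, those of glycolysis (0.153), ATF4 (0.173), aminoacyl-tRNA synthetase (0.0685), proteasome (0.0685), amino acid and nucleotide synthesis (0.0579) and chaperone genes (0.0579) were lost. Matching also on length and GC content ended the call of oxidative phosphorylation genes (0.638), for which only 61 of 75 members had values to match.

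Among the largest increases of the knockdown in the authors' deposited table, the water channel gene AQP1 rose by 3.92 ± 0.28, the transcription factor gene MYRF by 2.67 ± 0.16 and the imprinted RNA H19 by 2.41 ± 0.18. The myosin gene MYH6 rose by 2.41 ± 0.22, the smooth muscle gene TAGLN by 2.38 ± 0.18, P3H2 by 2.27 ± 0.15 and the cardiac troponin gene TNNT2 by 2.22 ± 0.09 in the authors' deposited table. TIMP3, an inhibitor of metalloproteinases, rose by 2.29 ± 0.06 (adjusted p = 1.31e-285) in the authors' deposited table. Markers of fibroblast and mesenchymal cells were higher as a list (5 of 10 higher, 2 lower, 3 not called, 5 and 3 adjusted over the list alone, adjusted p = 0.00196), a call lost with ranks (0.196) and against random lists of like mean count (0.253). The epithelial keratin genes rose at low abundance, KRT8 by 4.88 ± 0.47 and KRT18 by 4.15 ± 0.35 in the authors' deposited table, at mean normalized counts of 65.3 and 80.8. The largest decreases in the authors' deposited table, besides CDK8, were GAGE1 at -2.51 ± 0.20, PHACTR2 at -1.36 ± 0.22, TEX264 at -1.33 ± 0.07 and DNAH10 at -1.24 ± 0.19. In all, 2000 of 15380 tested genes were higher and 2318 lower, and 366 and 32 of these changed by at least 1 on the log2 scale. With the log2 fold changes centred on their median the balance turned, to 2228 higher and 1884 lower. With p-values from a t distribution with 4 degrees of freedom 127 genes were called, and the fall of translation factors did not pass against random lists of like mean count (adjusted p = 0.0903).

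**Figure D2:**
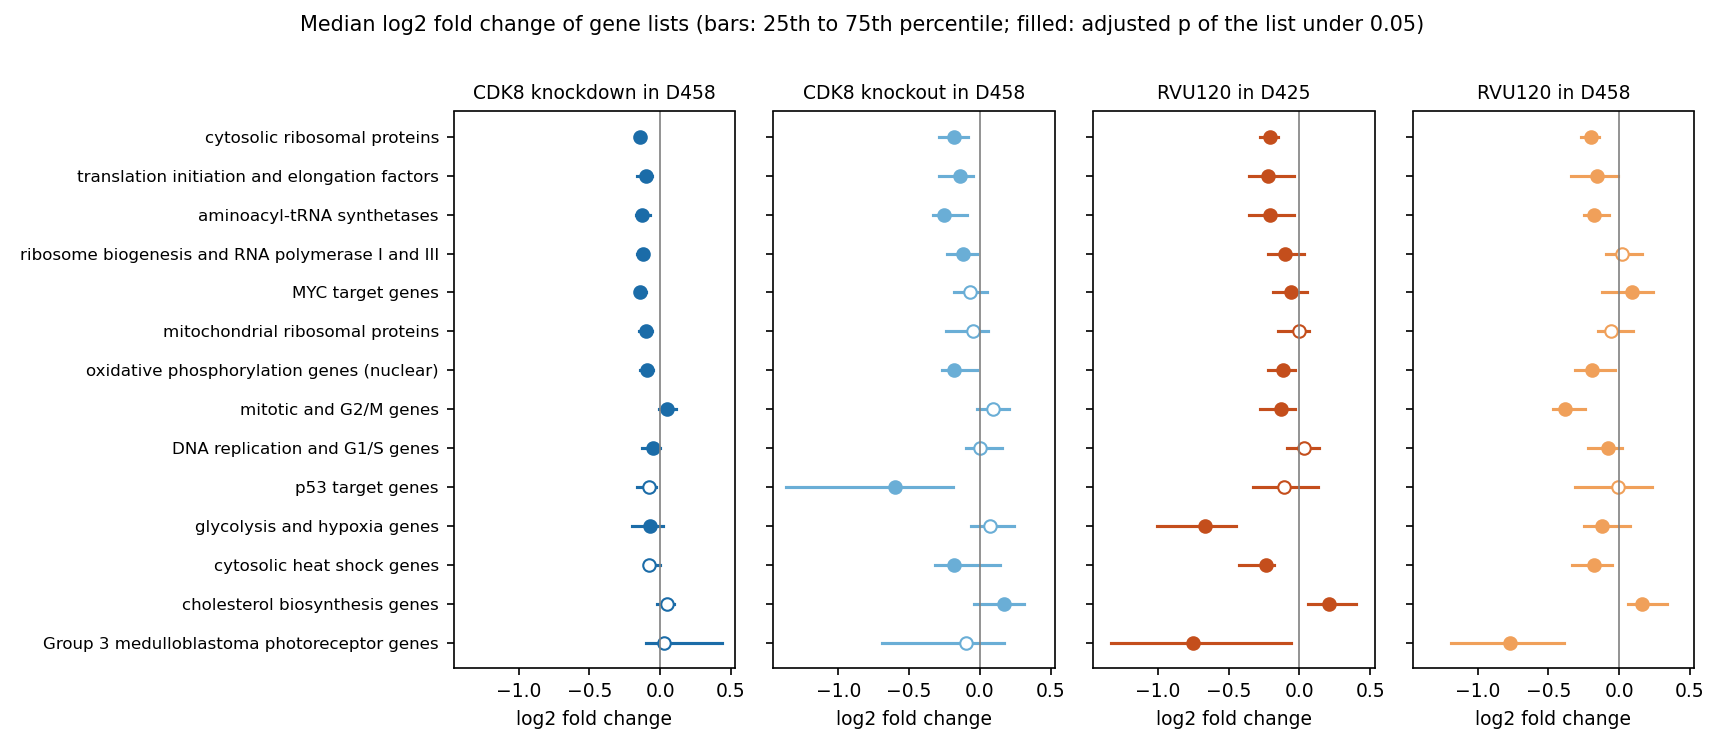
Median log2 fold change (x axis, perturbed over control) of 14 gene lists (y axis) in the 4 comparisons; bars span the 25th to 75th percentile of the members and filled points have a cameraPR adjusted p under 0.05. Cytosolic ribosomal proteins lie between -0.21 and -0.14 in all 4 panels, while mitotic genes reach -0.38 with RVU120 in D458 and glycolysis genes -0.67 with RVU120 in D425.

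In D458 more genes were called in the CDK8 knockout than in the knockdown, 3512 higher and 3469 lower of 16694 tested (3353 and 3616 when centred on the median). Some transcripts were all but lost. Chromosome 13 transcripts as a whole were lower in the knockout libraries (median -0.84). The knockout values here and in later comparisons cannot separate loss of CDK8 from effects of that difference, or of smaller shifts on other chromosomes. In the authors' deposited table the imprinted gene PEG10 fell by -9.48 ± 0.30 at a mean normalized count of 2850, FDCSP by -7.13 ± 0.09 and the nuclear pore gene NUP210 by -6.54 ± 0.29. PALD1 fell by -6.29 ± 0.44 and the desmosome gene DSP by -6.78 ± 0.53 in the authors' deposited table. TIMP3, which rose in the knockdown, fell by -10.07 ± 1.18 in the authors' deposited table, and GATA4 by -8.21 ± 0.85. The sizes fitted for TIMP3, PEG10 and GATA4 rest on few counts in the knockout libraries, and those of DSP and PALD1 have wider standard errors than that of PEG10. The receptor gene NOTCH1 fell by -3.54 ± 0.15, the basement membrane gene NID1 by -3.34 ± 0.12 and the synaptic vesicle gene SYP by -2.34 ± 0.06 in the authors' deposited table. The largest increases in the authors' deposited table were the myosin light chain gene MYL9 (4.77 ± 0.10), the angiopoietin gene ANGPT1 (4.05 ± 0.17), ADAMTS8 (3.19 ± 0.15) and ST3GAL1 (3.12 ± 0.14). Next in the authors' deposited table came DTX4 (3.06 ± 0.13), RHAG (3.05 ± 0.23), NEGR1 (2.94 ± 0.24) and CCDC74A (2.83 ± 0.23). TGFB1 rose by 1.30 ± 0.06 and the collagen gene COL11A1 by 2.14 ± 0.04 in the authors' deposited table.

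Transcripts of the translation machinery were lower in the knockout as well. Cytosolic ribosomal protein genes fell in 62 of 79 members, with 2 higher and 15 not called (63 and 2 adjusted over the list alone, median -0.18, cameraPR adjusted p = 5.01e-23). Translation factors fell in 33 of 48, with 4 higher and 11 not called (35 and 4 adjusted over the list alone, median -0.14, adjusted p = 8.58e-13). The elongation factor gene EEF2 fell by -0.87 ± 0.02 in the authors' deposited table. Aminoacyl-tRNA synthetases fell in 16 of 22, with 2 higher and 4 not called, the same adjusted over the list alone (median -0.25, adjusted p = 4.33e-06). Ribosome biogenesis genes were lower in 42 of 83, higher in 13 and not called in 28 (44 and 15 adjusted over the list alone, median -0.12, adjusted p = 0.00517, and 0.195 at a preset correlation of 0.05). MYC target genes were lower in 24 of 58, higher in 11 and not called in 23 (24 and 13 adjusted over the list alone), and the list was not called (adjusted p = 0.127). With log2 fold changes in place of the statistic, ribosomal proteins, translation factors and ribosome biogenesis genes were not called (adjusted p = 0.994 each), and ribosome biogenesis turned upward.

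Targets of p53, the damage-response transcription factor, fell in the knockout in 21 of 28 members, with 4 higher and 3 not called (22 and 4 adjusted over the list alone, median -0.60, adjusted p = 1.71e-07). PHLDA3 changed by -2.47 ± 0.16, FDXR by -2.00 ± 0.12 and SESN1 by -0.88 ± 0.06 in the authors' deposited table. Nuclear oxidative phosphorylation genes fell in 44 of 75, with 12 higher and 19 not called (45 and 12 adjusted over the list alone, median -0.18, adjusted p = 0.000188, and 0.0583 at a preset correlation of 0.05). Cytosolic heat shock genes were lower as a list (9 of 17 lower, 6 higher, 2 not called, the same adjusted over the list alone, adjusted p = 0.000412). HSPB1, which encodes a small heat shock protein, stood at -2.28 ± 0.09 in the authors' deposited table. Cholesterol biosynthesis genes rose (15 of 30 higher, 7 lower, 8 not called, 16 and 7 adjusted over the list alone, median 0.17, adjusted p = 0.0149, and 0.161 at a preset correlation of 0.05). Neural stem and progenitor genes fell (8 of 25 lower, 3 higher, 14 not called, the same adjusted over the list alone, median -0.27, adjusted p = 0.0447, and 0.195 at a preset correlation of 0.05). Fibroblast and mesenchymal markers were higher in 5 of 12, lower in 1 and not called in 6, the same adjusted over the list alone, without a call of the list (adjusted p = 0.375). With ranks the heat shock genes were not called (adjusted p = 0.34), and against random lists of like mean count neither they nor the progenitor genes were (0.0845 each). With log2 fold changes in place of the statistic, heat shock, oxidative phosphorylation and aminoacyl-tRNA synthetase genes (0.994 each) and cholesterol genes (0.601) were not called.

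Genes of chromosome 13, which carries CDK8, were lower together in the knockout. Their median was -0.84 over 180 genes with a mean normalized count of at least 100, with a 25th percentile of -1.02 and a 75th of -0.63. The medians of the other 22 chromosomes lay between -0.19 and 0.15. Calls were uneven on some of them, with 380 higher and 75 lower on chromosome 2 and 24 and 144 on chromosome 22. On others they were near even, such as 168 and 157 on chromosome 11. The knockdown had 110 higher and 184 lower on chromosome 2 and 67 and 28 on chromosome 22, but was uneven on chromosome 19 (245 and 59). Leaving out chromosome 13 does not remove such shifts, and their cause was not tested. In the knockdown the chromosome 13 median was -0.02 over 193 genes. Of 281 tested chromosome 13 genes 183 fell and 10 rose in the knockout, among them RPL21 at -1.05 ± 0.03 in the authors' deposited table. Without chromosome 13 genes 6781 genes were called in the knockout, and the median of ribosomal protein genes, of which 1 of 79 lies there, was -0.18. CDK8 itself, at -1.60 in the authors' deposited table, lay below the 25th percentile of these genes. Of all genes called in the knockout, 545 rose and 834 fell by at least 1 on the log2 scale, and with a t distribution 3475 genes were called.

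**Figure D3:**
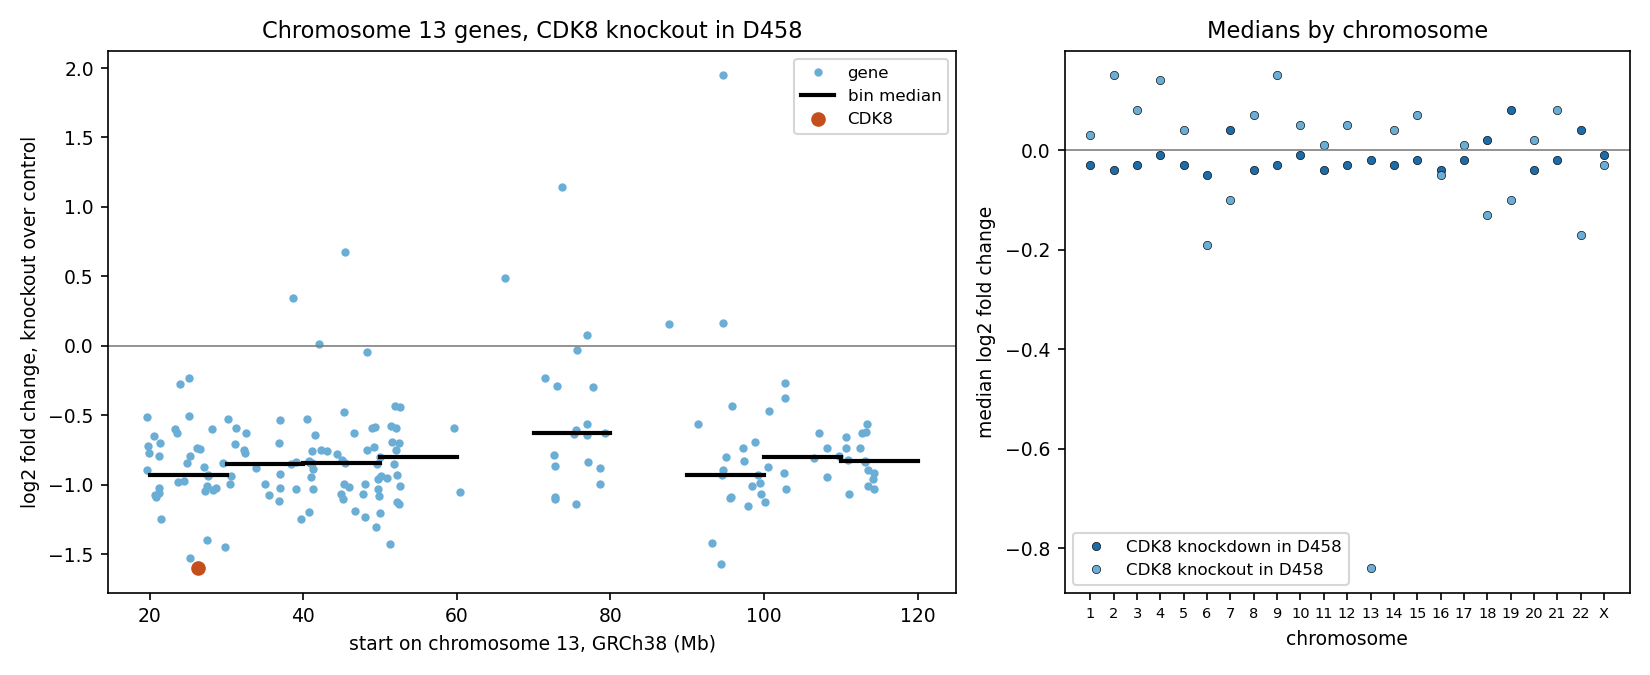
Left, log2 fold change (y axis, knockout over Cas9 control, from the authors' deposited table) of chromosome 13 genes with a mean normalized count of at least 100 by start position in Mb (x axis, GRCh38), with black lines for medians of 10 Mb bins with at least 10 genes; right, median log2 fold change (y axis) of each chromosome (x axis) in the knockdown and knockout. Bin medians lie between -0.93 and -0.63, and the chromosome 13 median is -0.84 in the knockout and -0.02 in the knockdown.

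RVU120 in D425 raised interferon-stimulated genes far above the DMSO level. Of 33 tested members 25 rose, 1 fell and 7 were not called (28 and 1 adjusted over the list alone, median 4.20, cameraPR adjusted p = 1.05e-49). The list covers antigen processing and interferon signalling. In the authors' deposited table the peptide transporter gene TAP1 rose by 8.61 ± 0.42 (adjusted p = 5.18e-89), the immunoproteasome gene PSMB9 by 7.67 ± 0.88 and IFITM3 by 5.21 ± 0.87. IRF9, which encodes a transcription factor, rose by 3.16 ± 0.20 (adjusted p = 4.33e-56) and B2M by 1.50 ± 0.12 in the authors' deposited table. USP18, a negative regulator of interferon signalling, fell by -1.50 ± 0.43 in the authors' deposited table. NLRC5, the activator of class I antigen presentation genes, rose by 9.37 ± 1.43 (adjusted p = 4.23e-09) in the authors' deposited table, the largest increase named at a mean normalized count of at least 100. Among the next were TAP2 at 6.80 ± 1.48, A2M at 6.45 ± 0.21, LGALS3BP at 6.03 ± 0.25 and tenascin C (TNC) at 6.03 ± 0.40 in the authors' deposited table. NLRC5, TAP1 and PSMB9 were close to 0 in DMSO, so the sizes of their increases are poorly determined. Those of TAP2 and IFITM3, with standard errors of 1.48 and 0.87, are not well determined either.

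Glycolysis and hypoxia genes fell in D425 in 27 of 34 members, with 0 higher and 7 not called, the same adjusted over the list alone (median -0.67, adjusted p = 6.81e-38). Hexokinase 2 (HK2) fell by -1.02 ± 0.10, GAPDH by -0.66 ± 0.09, ENO1 by -0.59 ± 0.09, BNIP3 by -1.27 ± 0.11 and NDRG1 by -1.01 ± 0.10 in the authors' deposited table. The photoreceptor program of Group 3 medulloblastoma fell in 16 of 33 members, with 1 higher and 16 not called, the same adjusted over the list alone (median -0.75, adjusted p = 2.46e-17). GUCA1A, an activator of retinal guanylate cyclase, stood at -2.83 ± 0.14 in the authors' deposited table. That was the largest fall among called genes with a mean normalized count of at least 100. GNB3 fell by -1.45 ± 0.12 and PDE6A, a rod phosphodiesterase, by -1.36 ± 0.11 in the authors' deposited table. Other large decreases in the authors' deposited table were LRTM1 (-2.75 ± 0.27), DIAPH2-AS1 (-2.63 ± 0.37), FAM19A4 (-2.51 ± 0.19), RNF144B (-2.28 ± 0.27), GUCA1B (-2.26 ± 0.18), SEMA3C (-2.15 ± 0.35) and CRB1 (-2.06 ± 0.28).

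TGF-beta and SMAD target genes rose with RVU120 in D425 (7 of 19 higher, 0 lower, 12 not called, 9 adjusted over the list alone, median 0.33, adjusted p = 3.62e-07). ID1 rose by 1.05 ± 0.11, ID3 by 1.25 ± 0.16 and the cell cycle inhibitor gene CDKN2B by 3.46 ± 0.32 in the authors' deposited table. Cholesterol biosynthesis genes rose (8 of 29 higher, 0 lower, 21 not called, 10 adjusted over the list alone, median 0.21, adjusted p = 6.43e-06). SC5D, a sterol desaturase gene, rose by 1.60 ± 0.11 in the authors' deposited table. Wnt target genes rose (4 of 13 higher, 0 lower, 9 not called, the same adjusted over the list alone, median 0.54, adjusted p = 0.0093). Cytosolic heat shock genes fell (6 of 16 lower, 0 higher, 10 not called, 8 adjusted over the list alone, median -0.24, adjusted p = 4.14e-05). Fibroblast and mesenchymal markers were higher as a list (3 of 10 higher, 1 lower, 6 not called, 4 and 1 adjusted over the list alone, median 0.02, adjusted p = 0.00249). The matrix genes LUM and DCN rose by 3.88 ± 0.24 and 1.66 ± 0.19 in the authors' deposited table. Immune markers had 0 of 5 members called by DESeq2 and no call of the list (adjusted p = 0.836). With ranks the fibroblast markers were not called (adjusted p = 0.567), and against random lists of like mean count neither they (1) nor the heat shock genes (0.0887) were. With log2 fold changes in place of the statistic, fibroblast (0.13), heat shock (0.158), cholesterol (0.341) and aminoacyl-tRNA synthetase genes (0.231) were not called.

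Cytosolic ribosomal protein genes fell in D425 in 13 of 79 members, with 0 higher and 66 not called (20 lower adjusted over the list alone, median -0.21, adjusted p = 2.38e-07). RPS12 fell by -0.72 ± 0.13 and RPSA by -0.55 ± 0.10 in the authors' deposited table. Translation factors fell in 17 of 48, with 0 higher and 31 not called (21 lower and 1 higher adjusted over the list alone, median -0.22, adjusted p = 3.16e-07). Aminoacyl-tRNA synthetases fell in 8 of 22, with 1 higher and 13 not called (11 and 1 adjusted over the list alone, adjusted p = 0.00203). Ribosome biogenesis genes were lower (12 of 83 lower, 0 higher, 71 not called, the same adjusted over the list alone, median -0.10, adjusted p = 0.00933, and 0.167 at a preset correlation of 0.05). MYC target genes were also lower (5 of 58 lower, 0 higher, 53 not called, the same adjusted over the list alone, median -0.06, adjusted p = 0.0453, and 0.258 at a preset correlation of 0.05). In all, 700 of 14212 tested genes were higher and 910 lower, 278 and 176 of them by at least 1 on the log2 scale. Against random lists of like mean count the ribosomal protein fall did not pass (adjusted p = 0.265). With a t distribution with 2 degrees of freedom in place of the normal of DESeq2, 0 genes were called, with 612 at an unadjusted p under 0.05. So few degrees of freedom let almost no statistic pass adjustment over 14212 genes, so the 0 was nearly fixed in advance.

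Further D425 calls were lost at the preset correlation of 0.05. Mitotic and G2/M genes were lower in 6 of 53, higher in 0 and not called in 47, the same adjusted over the list alone (median -0.13, adjusted p = 0.00225, and 0.0723 at 0.05). Of 75 oxidative phosphorylation genes 8 were lower, 0 higher and 67 not called, the same adjusted over the list alone (adjusted p = 0.00806, and 0.159 at 0.05). Amino acid and nucleotide synthesis genes were lower in 8 of 34, higher in 1 and not called in 25 (11 and 1 adjusted over the list alone, adjusted p = 0.00911, and 0.0962 at 0.05). Endoplasmic reticulum chaperones were higher in 3 of 23, lower in 0 and not called in 20 (4 higher adjusted over the list alone, adjusted p = 0.0453, and 0.167 at 0.05). Of 17 replication-dependent histone genes 1 was higher, 0 lower and 16 not called, the same adjusted over the list alone (adjusted p = 0.0453, and 0.16 at 0.05). Autophagy and lysosome genes were higher in 5 of 41, lower in 0 and not called in 36, the same adjusted over the list alone (adjusted p = 0.043, and 0.203 at 0.05).

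RVU120 in D458 lowered mitotic and photoreceptor transcripts and raised MYC. Mitotic and G2/M genes fell in 44 of 53 members, with 1 higher and 8 not called (46 and 1 adjusted over the list alone, median -0.38, cameraPR adjusted p = 1.81e-22). HMGB2, a chromatin protein, fell by -0.77 ± 0.06, the condensin gene SMC4 by -0.65 ± 0.05 and the topoisomerase gene TOP2A by -0.47 ± 0.04 in the authors' deposited table. The photoreceptor program fell in 21 of 34, with 2 higher and 11 not called (21 and 3 adjusted over the list alone, median -0.77, adjusted p = 3.1e-18). The cone arrestin gene ARR3 fell by -2.76 ± 0.29, GUCA1A by -2.11 ± 0.07 (adjusted p = 6.41e-182) and GNB3 by -1.20 ± 0.04 in the authors' deposited table. The largest fall named in the authors' deposited table, at a mean normalized count of at least 100, was EGR1, an immediate-early transcription factor. It stood at -5.99 ± 0.35 (adjusted p = 1.02e-62), and FOS fell by -3.98 ± 0.47 in the authors' deposited table. The immediate-early list was not called (4 of 28 higher, 5 lower, 19 not called, 4 and 6 adjusted over the list alone, adjusted p = 0.845). Its median of 0.09 was positive and its mean statistic negative.

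The largest increases with RVU120 in D458 in the authors' deposited table were the epithelial gene EPPK1 (3.79 ± 0.14), NID1 (2.90 ± 0.14), KIF26A (2.87 ± 0.36) and the dopamine receptor gene DRD2 (2.82 ± 0.27). Next in the authors' deposited table came CHST11 (2.55 ± 0.20), SEZ6 (2.51 ± 0.23), the vesicle release gene CADPS (2.35 ± 0.08) and IL17B (2.28 ± 0.29). The linker histone gene H1F0 fell by -2.07 ± 0.12, clusterin (CLU) by -2.06 ± 0.13, PAPPA2 by -2.64 ± 0.24, SLC13A2 by -2.55 ± 0.27 and LIMD2 by -2.11 ± 0.33 in the authors' deposited table. Cytosolic heat shock genes fell (7 of 17 lower, 0 higher, 10 not called, 10 adjusted over the list alone, median -0.18, adjusted p = 6.44e-10). HSPA8 fell by -0.48 ± 0.03 in the authors' deposited table. Cholesterol biosynthesis genes rose (15 of 30 higher, 1 lower, 14 not called, 16 and 1 adjusted over the list alone, median 0.16, adjusted p = 3.82e-07). SC5D rose by 1.39 ± 0.06 in the authors' deposited table.

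Ribosomal protein genes fell with RVU120 in D458 in 58 of 79 members, with 1 higher and 20 not called (64 and 1 adjusted over the list alone, median -0.20, adjusted p = 3.73e-18). Translation factors fell in 27 of 47, with 3 higher and 17 not called (30 and 4 adjusted over the list alone, median -0.16, adjusted p = 4.03e-12). Aminoacyl-tRNA synthetases fell in 12 of 22, with 2 higher and 8 not called, the same adjusted over the list alone (adjusted p = 0.00392). Oxidative phosphorylation genes fell in 32 of 75, with 1 higher and 42 not called (35 and 1 adjusted over the list alone, median -0.19, adjusted p = 8.05e-07). Glycolysis genes fell in 16 of 33, with 0 higher and 17 not called (16 lower and 2 higher adjusted over the list alone, adjusted p = 0.000371). Of 32 proteasome genes 17 were lower, 1 higher and 14 not called (18 and 2 adjusted over the list alone, adjusted p = 0.000918). MYC target genes were slightly higher (19 of 58 higher, 9 lower, 30 not called, 22 and 12 adjusted over the list alone, median 0.09, adjusted p = 0.045, and 0.276 at a preset correlation of 0.05). Among them NOLC1 stood at 0.34 ± 0.04, NOP2 at 0.51 ± 0.06 and NPM1 at -0.49 ± 0.04 in the authors' deposited table. Ribosome biogenesis genes had 20 of 83 higher, 13 lower and 50 not called (21 and 13 adjusted over the list alone) and no call (adjusted p = 0.156). In all, 2006 of 14515 tested genes were higher and 2403 lower, 267 and 251 of them by at least 1 on the log2 scale, and centred on the median 2223 were higher and 2159 lower. Against random lists of like mean count the falls of ribosomal proteins and translation factors (adjusted p = 0.337 each), glycolysis genes (0.877), heat shock genes (0.402) and aminoacyl-tRNA synthetases (0.104) did not pass. With log2 fold changes in place of the statistic, glycolysis (0.516), heat shock (0.212), aminoacyl-tRNA synthetase (0.445), proteasome (0.245), oxidative phosphorylation (0.0866) and cholesterol genes (0.152) were not called. Matching also on length and GC content ended the calls of proteasome (0.162) and oxidative phosphorylation genes (0.156). For the latter only 61 of 75 members had values to match, with a median of -0.15. With a t distribution with 2 degrees of freedom in place of the normal, 0 genes were called, with 1707 at an unadjusted p under 0.05. This 0 too was nearly fixed in advance by so few degrees of freedom.

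Several D458 calls with RVU120 did not hold at the preset correlation of 0.05. Replication-dependent histone genes were higher in 6 of 17, lower in 0 and not called in 11, the same adjusted over the list alone (median 0.66, adjusted p = 0.011, and 0.0577 at 0.05). HIST1H2BK rose by 1.37 ± 0.09 in the authors' deposited table. Of 23 endoplasmic reticulum chaperones 8 were higher, 0 lower and 15 not called, the same adjusted over the list alone (adjusted p = 0.0251, and 0.126 at 0.05). TGF-beta and SMAD target genes were higher in 7 of 19, lower in 1 and not called in 11, the same adjusted over the list alone (adjusted p = 0.045, and 0.163 at 0.05). DNA replication and G1/S genes were lower in 15 of 57, higher in 3 and not called in 39, the same adjusted over the list alone (adjusted p = 0.0401, and 0.276 at 0.05). Interferon-stimulated genes were higher in 4 of 19, lower in 3 and not called in 12, the same adjusted over the list alone, without a call of the list (adjusted p = 0.954). Neither fibroblast markers (0 of 10 higher and 1 lower by DESeq2, adjusted p = 0.954) nor immune markers (0 of 6 called, adjusted p = 0.946) were called.

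Whether the 2 lines answered RVU120 alike was asked by setting both tables side by side. Photoreceptor genes, ribosomal proteins and cholesterol biosynthesis genes moved the same way in both lines, whereas interferon-stimulated, glycolysis and mitotic genes moved to different degrees. Over 13543 genes tested in both, 291 were higher in both (89 expected, Fisher's exact p = 6.9e-90) and 598 lower in both (156 expected, p = 1.2e-258). Within bins of mean normalized count, 91 and 220 were expected. The number going opposite ways was 59, so 93.8% of the genes called in both had the same direction. Across genes, which are not independent replicates, the log2 fold changes had r = 0.42 and rho = 0.49. The effect differed at 611 genes, 258 of them with the higher value in D425 and 353 with the lower. Interferon-stimulated genes lay 1.65 higher in D425 by the median of 17 genes (adjusted p = 4.69e-28), and LGALS3BP by 7.61 ± 0.49 (adjusted p = 5.14e-51). Glycolysis genes lay lower in D425, with a median difference of -0.55 (adjusted p = 4.69e-28), HK2 at -1.13 ± 0.12. Mitotic genes were lowered less in D425 (median difference 0.20, adjusted p = 3.99e-07). MYC target and ribosome biogenesis genes lay lower in D425 (-0.15 and -0.14, adjusted p = 3.27e-05 and 1.67e-05), as did MYC itself (-0.37 ± 0.10, adjusted p = 0.0104). Fibroblast markers differed as a list as well (median difference 0.06 over 8 genes, adjusted p = 3.83e-05), but singly 2 passed with the higher value in D425 and 1 with the lower. For photoreceptor genes the difference was -0.04 (adjusted p = 0.302) and for ribosomal proteins -0.01 (adjusted p = 0.864). With a t distribution 0 differences passed the test of the difference, with 779 at an unadjusted p under 0.05. With a t distribution in place of the normal of DESeq2, 0 genes were called the same way in both lines, as neither line had calls under it, with 248 at an unadjusted p under 0.05 in both.

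**Figure D4:**
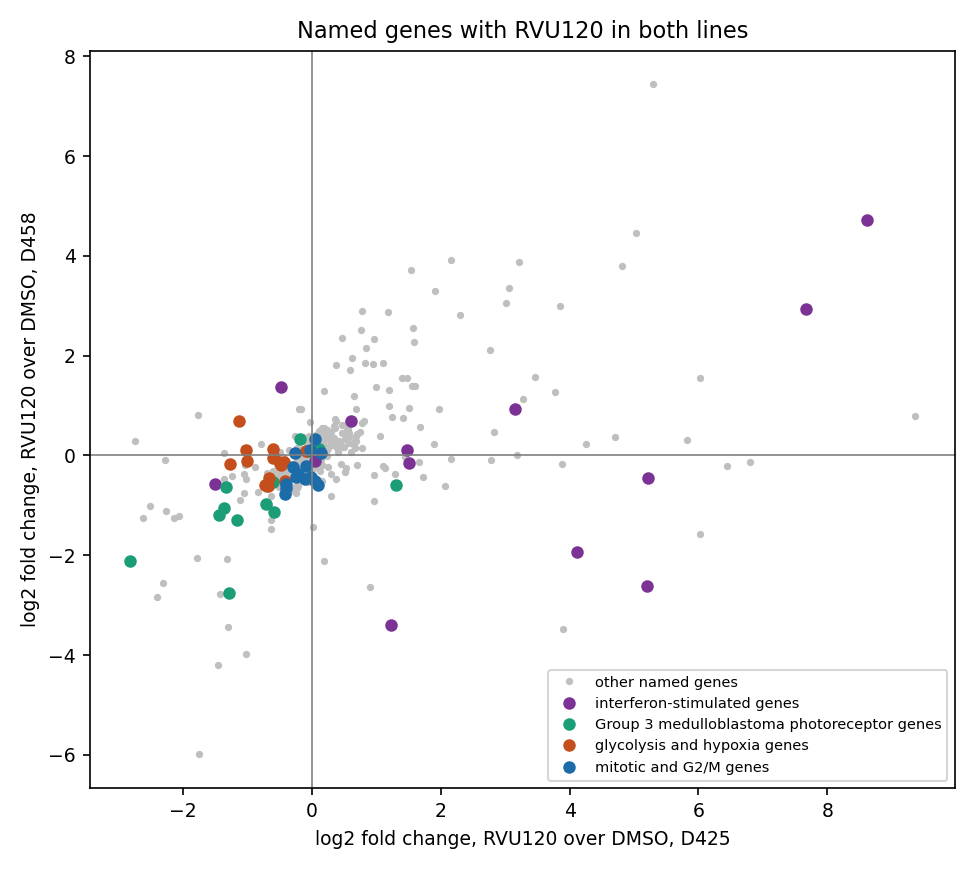
Log2 fold change with RVU120 in D425 (x axis) and D458 (y axis), both from the authors' deposited tables, for the named genes; colours mark members of 4 gene lists. GUCA1A lies low in both lines, at -2.83 in D425 and -2.11 in D458.

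The CDK8 transcript was lower in both knockdown and knockout, with a difference of 0.18 ± 0.09 that did not pass (adjusted p = 0.0772), but many other transcripts moved apart. In the knockout chromosome 13 genes as a whole had a median of -0.84, so the like falls do not show an equal loss of CDK8 function. Of 15261 genes tested in both, 743 were higher in both (452 expected, Fisher's exact p = 4.8e-57) and 786 lower in both (520 expected, p = 1.4e-43). Another 1052 went opposite ways (448 with 447 expected, and 604 with 526 expected), so 59.2% of the genes called in both shared their direction. Within bins of mean normalized count the numbers expected were 465 higher in both, 690 lower in both, and 452 and 709 opposite. The log2 fold changes had r = -0.00 and rho = 0.04 across all these genes, and r = 0.13 and rho = 0.13 across the 10478 genes with a mean normalized count of at least 100 in both. The effect differed at 6266 genes, PEG10 by 9.41 ± 0.30, FDCSP by 7.22 ± 0.12 and NID1 by 4.01 ± 0.12 (knockdown minus knockout). MYC differed by -0.25 ± 0.03 (adjusted p = 8.38e-14). NPTX1, a neuronal pentraxin, fell by -0.59 ± 0.03 in the knockdown and rose by 0.48 ± 0.03 in the knockout in the authors' deposited table. Targets of p53 lay 0.53 higher in the knockdown (adjusted p = 9.53e-06). Chaperones of the endoplasmic reticulum (-0.18, adjusted p = 0.0252), glycolysis genes (-0.14, 0.0115) and amino acid and nucleotide synthesis genes (-0.12, 0.0252) lay lower in the knockdown, but not at a preset correlation of 0.05 (0.232, 0.232 and 0.273). Ribosomal protein genes differed by 0.05 without a call (adjusted p = 0.0536). With a t distribution 51 genes were called the same way in both.

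The CDK8 knockdown and knockout differed from RVU120 in D458 in MYC and in several gene lists, both of them in mitotic and photoreceptor genes. For the knockdown the shared calls showed no common direction. The knockout contrasts carry the chromosome 13 difference as well. For the knockdown, 598 of 14422 genes were lower in both (386 expected, Fisher's exact p = 4.3e-35, but 621 expected within bins of mean normalized count) and 278 higher in both (266 expected, p = 0.21, and 263 within bins). Opposite calls were also above their expected numbers, 420 (320 expected, 298 within bins) and 427 (320 expected, 409 within bins), so 50.8% of the genes called in both shared their direction, with r = 0.05 across genes. For the knockout, 884 of 14480 were lower in both (560 expected, Fisher's exact p = 1.3e-60, and 688 within bins) and 692 higher in both (477 expected, p = 7e-32, and 561 within bins). Opposite calls numbered 640 (572 expected, 706 within bins) and 428 (468 expected, 521 within bins), so 59.6% shared their direction, with r = 0.03 across genes. Mitotic genes lay higher in the genetic perturbations than with RVU120, by 0.42 in the knockdown (adjusted p = 4.43e-25) and 0.46 in the knockout (adjusted p = 1.09e-15). Photoreceptor genes lay higher by 0.85 (adjusted p = 1.83e-17) and 0.30 (adjusted p = 9.14e-05). In the knockdown MYC targets (-0.20, adjusted p = 6.82e-07), ribosome biogenesis genes (-0.15, 5.05e-06), endoplasmic reticulum chaperones (-0.25, 5.05e-06), cholesterol genes (-0.11, 0.000122) and ATF4 genes (-0.15, 0.00216) lay lower than with RVU120 and heat shock genes higher (0.10, 6.11e-06). In the knockout p53 targets lay lower (-0.42, adjusted p = 0.000121) and glycolysis genes higher (0.18, 0.000851). Differences lost at a preset correlation of 0.05 were those of ribosomal proteins and translation factors in the knockdown (0.06 and 0.05, adjusted p = 0.0444 each, and 0.382 and 0.355 at 0.05). The same held in the knockout for ribosome biogenesis genes, MYC targets and histone genes (-0.16, -0.14 and -1.20, adjusted p = 0.00319, 0.0205 and 0.0205, and 0.195, 0.297 and 0.142 at 0.05). The photoreceptor list itself was not called in the knockdown (13 of 35 higher, 8 lower, 14 not called, 14 and 9 adjusted over the list alone, adjusted p = 0.184). In the knockout it was not called either (9 of 34 higher, 11 lower, 14 not called, 10 and 11 adjusted over the list alone, adjusted p = 0.48). MYC differed from its value with RVU120 by -0.79 ± 0.04 in the knockdown and -0.53 ± 0.04 in the knockout. CADPS differed by -2.86 ± 0.13 between knockdown and RVU120, and EGR1 by 6.25 ± 0.38. The effect differed at 4346 genes for the knockdown and 5335 for the knockout. With a t distribution in place of the normal of DESeq2, 0 genes were called the same way, as RVU120 had 0 calls under it, with 399 and 667 at an unadjusted p under 0.05. At an adjusted p under 0.01 the shared calls numbered 533 and 1049.

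Translation factors and aminoacyl-tRNA synthetases stood out among the genes lower in all 4 comparisons. Of 13503 genes tested in all 4, 129 were lower and 42 higher throughout, against means of 6.53 and 2.87, and at most 14 and 9, in 1000 random reassignments of the calls. Abundant genes are called more often, and with calls reassigned within 20 bins of mean normalized count the means were 29.3 and 3.04, and the most 48 and 9. Lower in all 4 were 13 of 47 translation factors (3.1 expected within bins, exact test adjusted p = 7.98e-05) and 5 of 22 aminoacyl-tRNA synthetases (0.944 expected, adjusted p = 0.0231). This exact test was added after the data were seen. It treats genes as independent, so correlation between members of a list was not allowed for. No other list passed this test in either direction. Among those that did not were ribosomal proteins (12 of 79, adjusted p = 0.178), heat shock genes (3 of 16, 0.276), glycolysis genes (4 of 33, 0.178), photoreceptor genes (3 of 31, 0.158), oxidative phosphorylation genes (5 of 75, 0.178), ribosome biogenesis genes (5 of 83, 0.21) and MYC targets (3 of 58, 0.776). In at least 3 comparisons 37 of the 79 ribosomal protein genes were lower. No number expected at their abundance was worked out for this count, so it does not set them apart. In the order knockdown, knockout, RVU120 in D425 and RVU120 in D458, the authors' deposited tables give RPS12 at -0.21, -0.72, -0.72 and -0.67 and RPSA at -0.13, -0.26, -0.55 and -0.43. In the same order and tables, the authors' deposited values put the initiation factor gene EIF4B at -0.18, -0.37, -0.56 and -0.50, PABPC4 at -0.88, -0.41, -0.84 and -0.73, and NPM1 at -0.16, -0.13, -0.49 and -0.49. Higher in all 4 in the authors' deposited tables were the metalloproteinase gene ADAM28 (0.92, 1.63, 1.55 and 1.39), ADAMTSL1 (1.84, 2.05, 3.77 and 1.27) and TECTA (0.81, 1.41, 2.76 and 2.11). The authors' deposited tables also gave increases for the sorting receptor gene SORL1 (1.05, 0.77, 0.83 and 1.85), the cytokine gene IL17B (1.54, 1.40, 1.59 and 2.28), the cadherin gene CDH11 (0.81, 1.54, 0.68 and 0.94) and FEZF1-AS1 (0.60, 1.81, 1.47 and 1.55). FAM57B fell throughout in the authors' deposited tables, at -0.82, -1.60, -0.64 and -1.47. At an adjusted p under 0.01, 87 genes were called the same way in all 4. With a t distribution in place of the normal of DESeq2 0 were, as RVU120 had 0 calls under it, with 64 at an unadjusted p under 0.05 in all 4.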

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

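The tests of explanations below were chosen after the patterns had been seen, and all but those against matched random lists were chosen only after the result was seen.

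What RVU120 did differed between D425 and D458, by a test of the difference, at 611 genes and in 11 gene lists. By the median of D425 minus D458, interferon-stimulated genes differed by 1.65, mitotic genes by 0.20, proteasome genes by 0.17, TGF-beta and SMAD targets by 0.12, DNA replication genes by 0.11, autophagy and lysosome genes by 0.08 and fibroblast markers by 0.06. Glycolysis and hypoxia genes differed by -0.55, ATF4 and integrated stress response genes by -0.16, MYC targets by -0.15 and ribosome biogenesis genes by -0.14. At a preset correlation of 0.05 between genes, DNA replication and ATF4 genes (adjusted p = 0.111 each) and TGF-beta targets and autophagy genes (0.149 each) no longer passed. Of the 8 fibroblast markers, singly 2 passed with the higher value in D425 and 1 with the lower. Among genes, LGALS3BP differed by 7.61, A2M by 6.68, GLUL by 1.48 and CADPS by -1.87.

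Interferon-stimulated genes rose in D425 with RVU120 and not detectably in D458. RNA of immune cells or fibroblasts at the level of CCL2, a chemokine chosen after its values were seen with a mean normalized count of 8890, is argued against by 11 immune markers that summed to 273 and by COL1A1, COL1A2, COL3A1 and FN1, which summed to 201. The fixed list of fibroblast markers was nevertheless higher in the same comparison (adjusted p = 0.00249, and 0.0135 at a preset correlation of 0.05), with LUM at 3.88 and DCN at 1.66 in the authors' deposited table, so a smaller share of such cells stays open. Whether 1 of the 2 RVU120 libraries alone carried the rise cannot be told apart from a rise in both, because there are no values per library: the standard errors of 12 called members were 1.14 times those of genes of like mean count by the median (0.975 to 4.07). A direct effect of the inhibitor, an answer to an interferon made by the cells (IFNG, also chosen after its values were seen, went from 0.195 to 29.5 normalized counts by the deposited mean and fold) and a difference between the cultures all stay open.

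Chromosome 13 transcripts were lower together in the CDK8 knockout, with a median of -0.84. Loss of CDK8 function as the cause is argued against by the knockdown, where the chromosome 13 median lay -0.0047 from that of the other chromosomes, and a bias of abundance, length or GC content by matched random lists, among which the median lay at percentile 0. A lower copy number of chromosome 13 may account for it, as every 10 Mb bin with at least 10 genes was low, the highest at -0.63. Whether the change arose with the editing or in the cells that were grown out was not tested, and the DNA was not analysed here.

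Cytosolic ribosomal protein transcripts were lower in all 4 comparisons. Against random lists matched on abundance, length and GC content the list median lay at percentile 0 in the knockdown and 0 in the knockout, as it did with mean count alone. The list thus fell more than the genes matched to it there. Correlation between members was not allowed for. The matching set no limit on distance and its closeness was not checked, so those properties are not excluded. With RVU120 they cannot be told apart from an effect of the inhibitor: the percentiles were 2.11 in D425 and 1.89 in D458, but 8.54 and 6.84 with mean count alone, and after adjustment over all lists neither line passed (adjusted p = 0.073 and 0.131, and 0.265 and 0.337 with mean count alone). In the knockout, lower dosage of chromosome 13 could directly lower only the 1 of 79 ribosomal protein genes that lies there. The other 61 of the 62 members called lower lie on other chromosomes. The dosage of those chromosomes, whose medians lay between -0.19 and 0.15, was not tested. An indirect effect of other chromosome 13 genes was not tested, and slower growth and changed MYC activity stay open. A scaling factor common to all genes would lower the matched lists as much. Their median was -0.08 beside -0.14 for ribosomal proteins in the knockdown, and -0.03 beside -0.18 in the knockout. That argues against such scaling as the whole cause there, and with RVU120 scaling stays open.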

How the results depend on the processing

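The tests with lists matched on abundance, length and GC content, and those without chromosome 13 genes, were added after the data had been seen; of these, leaving out chromosome 13 was chosen only after the result was seen. No paired analysis was possible because the tables hold no values per library, and for the same reason leaving out single libraries, other splits of the samples, other normalizations and an estimated correlation could not be run. For the results that answer a comparison, 146 alternatives kept the direction and the side of the threshold (or a count within 1.5 times), 24 were weaker, 1 was stronger, 29 moved a count further and 1 reversed. For other gene lists 560 kept both, 90 were weaker, 22 stronger and 2 reversed. CDK8 kept its direction and its side of the threshold in every comparison under the 3 alternatives run for it. For what follows, the cause was not tested unless it is given.

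A minimum absolute log2 fold change of 1 left 398 genes in the knockdown, 1379 in the knockout, 454 with RVU120 in D425 and 518 with RVU120 in D458, fewer by construction. A t distribution with few degrees of freedom widens each p-value: it left 127 and 3475 genes in the knockdown and knockout, and 0 and 0 for RVU120 in D425 and D458, where 612 and 1707 genes had an unadjusted p under 0.05. Under it 51 genes were called the same way in knockdown and knockout and 0 in each other pair and in all 4, where 248, 399, 667 and 64 genes passed at an unadjusted p under 0.05 (RVU120 in both lines, knockdown and RVU120, knockout and RVU120, all 4). Genes whose effect differed numbered 0 for RVU120 in both lines (779 at an unadjusted p under 0.05), 1838 for the knockdown and RVU120, and 2953 for the knockout and RVU120. An adjusted p under 0.01 left 537, 533 and 1049 genes called the same way in those 3 pairs and 87 in all 4. Leaving out the knockdown gave 405 genes shared by the other 3 comparisons, and leaving out the knockout 283, more by construction.

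With log2 fold changes in place of the statistic, the knockout adjusted p was 0.994 for ribosomal proteins, translation factors and ribosome biogenesis, the last reversed to upward. It was 0.18 for ribosome biogenesis and 0.292 for MYC targets with RVU120 in D425, and 0.152 for translation factors and 0.92 for MYC targets in D458. The knockdown's mitotic genes turned downward (adjusted p = 0.632). Other lists called fell from 13 to 4 in the knockdown, from 6 to 2 in the knockout, from 15 to 5 in D425 and from 12 to 4 in D458. With a preset correlation of 0.05 the adjusted p was 0.195 for ribosome biogenesis in the knockout, 0.167 for it and 0.258 for MYC targets in D425, and 0.276 for MYC targets in D458, and 3 and 9 other lists were called in the knockout and D425. With ranks it was 0.0634 and 0.0582 for MYC targets in D425 and D458, and MYC targets passed in the knockout (0.0307). Genes with a mean normalized count of at least 100 gave 0.126 for MYC targets in D425.

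Against random lists matched on mean count, the adjusted p was 0.0903 for translation factors in the knockdown, 0.265 for ribosomal proteins, 0.0707 for ribosome biogenesis and 0.745 for MYC targets in D425, and 0.337 for both ribosomal proteins and translation factors in D458. The kinase module median in the knockdown turned upward (0.842). Matched also on length and GC content, the values were 0.155 for translation factors in the knockdown, 0.073 and 0.431 for ribosomal proteins and MYC targets in D425, 0.131 and 0.281 for ribosomal proteins and translation factors in D458, where 6 other lists were called. Of simulated changes of 0.5, 40.8% were called with RVU120 in D425 and 82.5% in the knockdown, but the depth of single libraries is unknown and the RVU120 groups hold 2 libraries instead of 3, so what depth limits was not tested.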

Other observations

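The tests of muscle genes, those without chromosome 13 genes and the control-arm levels below were chosen only after the result was seen, the matching on length and GC content was added after the data had been seen, and the other lists and tests were fixed before.

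Skeletal muscle transcripts were present in D458 and rose with the CDK8 knockdown. Of 24 tested members of a list of 27 muscle genes, 19 were higher and 1 lower (median 1.75, cameraPR over n = 24 genes, p = 1.48e-71, and 6.63e-42 at a preset correlation of 0.05), but the list was written after the knockdown genes were seen and holds some of them, such as TNNT2 and MYH6. In the authors' deposited table the embryonic myosin gene MYH3 rose by 2.01 ± 0.06 at a mean normalized count of 1755, the troponin gene TNNI1 by 2.05 ± 0.06, desmin (DES) by 1.83 ± 0.08, the cardiac actin gene ACTC1 by 2.14 ± 0.13 and the muscle transcription factor gene MYOG by 0.89 ± 0.06. MYOD1, which starts muscle differentiation, changed by -0.15 ± 0.04 at a mean normalized count of 9653 in the authors' deposited table. Expression of muscle genes is known in some medulloblastomas, and the labels say nothing of it for these lines.

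A candidate explanation is that muscle genes rise with CDK8 loss by either method, which the knockout did not decide. There 12 of 25 members were higher and 5 lower, with a median of 0.07 and an unadjusted cameraPR p of 0.0363 that became 0.116 at a preset correlation of 0.05, and of the 19 members higher in the knockdown 11 were higher and 2 lower (median 0.32). Whether muscle genes rise with lower CDK8 kinase activity was not decided by RVU120 in D458. With it 2 of those 19 were higher and 4 lower, with a median of -0.23 and a 75th percentile of 0.20. The 19 were picked by their rise in the knockdown, so their 25th percentile of 1.05 there is no fair measure to set beside these. Of the members so left out, MYOD1 rose by 0.62 ± 0.06, NEB by 0.61 ± 0.05 and TTN by 0.43 ± 0.07 with RVU120 in D458 in the authors' deposited table, and ACTA1 was not called. Over all 23 tested members 5 were higher and 4 lower there (median 0.01, cameraPR over n = 23 genes, p = 0.201), and how far the kinase was inhibited is not given in the sources used here. In D425 the list went the other way: of 9 members tested 0 were higher by DESeq2 and 4 lower, with a median of -0.48 and an unadjusted cameraPR p of 0.00448 (0.0125 at a preset correlation of 0.05).

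NRL and CRX of the photoreceptor program, chosen after their values were seen, stood at different levels in the control arms of D458, without a test. Per 1000000 of the summed mean normalized count, and calculated from the deposited mean and fold, NRL stood at 34.3 with shNull, 3.98 with the Cas9 negative control and 59 with DMSO, and CRX at 30.9, 15.8 and 26.5. GNB3 stood at 802, 558 and 728 and PDE6H at 3.2, 4.09 and 6.89, so not every gene of the program was lowest with the Cas9 negative control. MYC was 2463, 2549 and 2410 and OTX2 1902, 1994 and 2096 in the same arms. The tables were normalized separately, so these levels are descriptive.

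Other lists showed no call in a comparison by cameraPR on the statistic. Interferon-stimulated genes had 5 of 21 higher and 1 lower in the knockdown (adjusted p = 0.151) and 5 of 27 higher and 7 lower in the knockout (0.769). Core Mediator subunits had 2 of 26 higher and 1 lower in the knockdown (adjusted p = 0.701), 5 higher and 9 lower in the knockout (0.413), 2 higher and 0 lower by DESeq2 with RVU120 in D425 (0.563) and 1 higher and 4 lower in D458 (0.954). Neuronal differentiation genes had 8 of 39 higher and 9 lower in the knockdown (adjusted p = 0.239) and 11 of 41 higher and 13 lower in the knockout (0.637, median -0.20 with a positive mean statistic), where STMN2 rose by 2.32 ± 0.07 and INA fell by -2.44 ± 0.14 in the authors' deposited table. With RVU120 they had 4 of 33 higher and 8 lower in D425 (adjusted p = 0.0928) and 5 of 36 higher and 10 lower in D458 (0.112). Immediate-early genes were not called in the knockdown (8 of 31 higher, 6 lower, adjusted p = 0.235), the knockout (5 of 31 higher, 9 lower, 0.408) or RVU120 in D425 (4 of 28 higher, 3 lower, 0.263). Astrocyte and oligodendrocyte markers were not called in any comparison (adjusted p = 0.69, 0.66, 0.563 and 0.954 in the order knockdown, knockout, RVU120 in D425 and in D458). Epithelial and endothelial markers had 2 of 4 higher and 0 lower by DESeq2 in the knockdown, too few for a list test, and 1 of 5 higher and 1 lower in the knockout (adjusted p = 0.829). With RVU120 they had 0 of 4 called by DESeq2 in each line. The 13 mitochondrially encoded genes were listed in 0 of the tables used here.

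Some lists without such a call passed under other ways of testing. In the knockdown, immediate-early genes were higher than random lists of like mean count (adjusted p = 0.00103) and than lists matched also on length and GC content (0.00266), and cholesterol genes were too (0.00266 and 0.00207). Neuronal differentiation genes were lower against both (0.0196 and 0.00434), and p53 targets lower with ranks (0.0283) and against lists of like mean count (0.0372). Histone genes were higher with ranks (0.0102) and against both kinds of random lists (0.0459 and 0.0289), and interferon-stimulated genes with log2 fold changes in place of the statistic (0.018). In the knockout interferon-stimulated genes had a median of -0.84 and were lower against both kinds of random lists (adjusted p = 0.00731 and 0.0165). Mitotic genes were higher there with ranks (0.00233), without chromosome 13 genes (0.0286) and against lists matched on count, length and GC content (0.0296), and TGF-beta targets without chromosome 13 genes (0.0498). Among genes with a mean normalized count of at least 100, neuronal genes were lower with RVU120 in D425 (adjusted p = 0.00199) and D458 (0.0312). In D458 ATF4 genes were higher than lists of like mean count (0.0165), and immediate-early genes lower by log2 fold changes (0.0359).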
